A study of Moesziomyces aphidis with 9 samples.

How the data were processed

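RNA sequencing data of 9 libraries from Moesziomyces aphidis DSM70725 were used. The main comparison had 3 libraries from glucose cultures and 3 from cultures with glucose and soybean oil, all prepared with the TruSeq RNA v2 kit and sequenced on a HiSeq2000 as 50 bp single reads. Per the labels, RNA was extracted from cells frozen after 114 h. The stranded libraries, 1 per medium, came from the TruSeq Stranded kit, and the paired-end library with 95 bp reads from soybean oil replicate 2. Since the labels give these 3 libraries the numbers of replicates already present, they were set against the same-numbered libraries and not added to the groups.

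The deposited gene files give RPKM values made by the authors, and the deposited junction lists give counts of reads that span each splice junction. Alignment was done with TopHat 1.4.1 according to the submitters' processing notes. The counting tool, the annotation and the genome build are not given in the sources used here. In the 7 unstranded and paired-end libraries the RPKM values were ratios of whole numbers. Read counts per gene, gene lengths and library totals were therefore worked out from them, and whole reads were recovered for 6952 of 6952 genes (100%) with a tolerance of 1e-06 read. On simulated data the same procedure recovered every read of 6908 of 6952 genes and 7 of 7 library totals. The totals ran from 8108888 to 11100455 reads in the 6 main libraries. The median gene length was 1655 bp, and 32.4% of lengths were multiples of 3. The deposited RPKM values of the stranded libraries have 2 decimals and none under 1, and 1 was taken to have been added to each. After subtracting 1, 96.5% of 201 low values on glucose and 98.0% of 299 with oil fell on whole reads within rounding (19.3% and 15.0% by chance), against 37.3% and 35.3% without subtraction (24.0% and 25.9% by chance). The 1 was therefore subtracted before use, and no reads were recovered. Each stranded library has 2 junction lists, and the labels do not explain how these differ. Both were used to count which introns were listed and for the reads of single introns, and entered no test.

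Genes were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with an intensity trend in the prior variance. Genes with a mean of at least 1 RPKM over the 6 libraries were tested, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. A change of at least 2-fold required a log2 fold change of at least 1 in size as well. Fold changes are soybean oil minus glucose on this scale, so they include the added 1 RPKM. RPKM values do not allow for a shift in RNA composition, and scaling by the median ratio and quantile normalization were tried as alternatives. On simulated reads with 200 changed genes and a dispersion of 0.025, the test found 97% of 2-fold and 100% of 4-fold changes and called 13 unchanged genes. The changed genes were drawn from those with a mean of at least 10 RPKM, so recovery among weaker genes was not measured. The dispersion was set, not estimated, and no simulated library deviated from its group as glucose replicate 3 did in the data. Recovery and false calls in the data may therefore differ.

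Genes to be named were chosen by a rule written before the data were examined. It covered members of 28 gene lists (among them mannosylerythritol lipid synthesis, fatty acid oxidation and cell wall), the 12 strongest rises and falls with a mean of at least 10 RPKM and no overlap between groups, the 5 most abundant genes of each medium, and the longest runs of changed neighbours. The lists are written as gene and product names, and the files carry identifiers alone and do not pair them with names. The lists were therefore not tested, and only the 2 strongest rises and 2 strongest falls are named, while the other groups are given as counts and ranges.

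Neighbouring genes were taken from consecutive identifier numbers within each of the number series, below and above 10000. Pairs in which both genes rose, or both fell, at least 2-fold were counted and compared with 10000 random orders of the tested genes, and runs of at least 4 genes with 1000 random orders. Whether identifiers follow the scaffolds is not stated in the sources used here.

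Introns were matched across libraries by scaffold, start, end and strand, with positions counted from 1. Junction reads were tested with the quasi-likelihood test of edgeR 4.0.16, with TMM factors and its filter on low counts. Competing splice sites, with at least 2 junctions of at least 10 reads over the 6 libraries, were tested with edgeR's differential splicing test and Simes p-values. On simulated junction reads the first test found 78% of 2-fold and 100% of 4-fold changes with 6 false calls among 2270 junctions. The second found 95% of 20 changed sites with 0 false calls, without missing junctions in the simulation. Changed junctions were drawn from those with a mean of at least 20 reads. Changed sites were drawn from those with 2 junctions of at least 100 reads each over the 6 libraries. Recovery among weaker junctions was not measured. In these simulations too the dispersion was set and no library deviated from its group. Introns of at most 1000 nt on the same strand and within 2000 nt of each other were joined into loci. The rule for the introns named in the text, and the scaffold regions, were chosen after the data were examined.

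Alternatives planned before the data were examined were other pseudocounts, filters and normalizations, limma without the trend, the replicate number as a block, leaving out each library, and DESeq2 1.42.0 and edgeR on the recovered reads. The closing section gives their effect. Other calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. No annotation, genome sequence or raw reads were used.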

Results

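Moesziomyces aphidis (formerly Pseudozyma aphidis) is a yeast-like basidiomycete fungus that secretes mannosylerythritol lipids, which are glycolipid surfactants. The series addressed the fungus's transcripts and their expression on different carbon sources. Strain DSM70725 was cultured for 114 h at 30 °C in yeast extract medium that held 40 g/l glucose. These cultures are labelled as not induced and their cells as blastospores. A second set of cultures received a further 70 g/l soybean oil, and the labels describe them as induced and filamentous, so medium and cell form changed together. Total RNA of 3 replicates per medium was sequenced as unstranded 50 bp single reads. Further libraries labelled with the numbers of these replicates were 2 stranded libraries, 1 per medium, and 1 paired-end library with 95 bp reads from soybean oil replicate 2. The files gave an RPKM value (reads scaled to gene length and library total) for each of 6952 genes and a list of splice junctions for each library. The 3 glucose libraries held 9957811, 9064758 and 9015790 reads, and the 3 soybean oil libraries 10190455, 11100455 and 8108888. The paired-end library held 31573726 reads. No total was worked out for the stranded libraries. Between 97.2% and 98.1% of the reads of the 6 main libraries lay in genes. A count of 0 in a library allows up to 3 reads, for counting error only.

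The first comparison asked which genes changed expression when soybean oil was added. At least 2-fold higher expression was found for 430 genes and at least 2-fold lower expression for 790 genes, out of 6486 tested. The risen genes took 4.24% ± 0.110 (SD, n = 3) of the reads in genes on glucose and 16.3% ± 0.363 with soybean oil. The fallen genes took 21.7% ± 1.15 (SD, n = 3) on glucose and 5.13% ± 0.145 with oil. Changes of at least 16-fold were seen in 32 risen and 32 fallen genes. The most abundant glucose transcripts were among those that fell: all 5 genes with the highest mean RPKM on glucose were at least 2-fold lower with oil, 3 of them with any of the 6 libraries left out. Of the other 2, the first had a log2 fold change of -0.81 without glucose replicate 3 and was not called without soybean oil replicate 3 (limma adjusted p 0.0532), and the second had -0.95 without glucose replicate 1. The gene with the highest mean RPKM with oil rose from 1978 ± 302 to 11371 ± 466 RPKM (SD, n = 3), a log2 fold change of 2.53 by limma. None of the 5 most abundant genes with oil was among the 5 most abundant on glucose, but the other 4 of these changed less than 2-fold: the log2 fold changes of 2 were 0.91 (limma adjusted p 0.0254 and 0.0272), and those of the remaining 2, which were not called, were 0.17 and 0.40 (0.443 and 0.103). The first 2 of these were not called without glucose replicate 2 or 3 or without soybean oil replicate 1 or 2 (limma adjusted p 0.0521 to 0.0963), and reached 2-fold without glucose replicate 1 (1.15 for both) or soybean oil replicate 3 (1.06 for both). These 2 had nearly equal values in each of the 6 libraries, such as 6658 and 6556 RPKM in glucose replicate 1. They may not be separate results, and whether they share reads was not tested.

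Without the limit on size, 3210 genes (49.5%) had a limma adjusted p under 0.05, of which 1392 were higher with oil and 1818 lower, and 3660 had an unadjusted p under 0.05. The excess of lower genes depended on the scaling: 1660 were higher and 1737 lower after median-ratio scaling, and 1708 higher and 1591 lower after quantile normalization. The median log2 fold change of all tested genes was -0.06. The values of the groups did not overlap in 3887 of the 6486 genes (59.9%), where chance alone gives 10%. Risen and fallen genes were spread unevenly over expression levels. Between a mean of 1 and 10 RPKM, 57 of 865 genes were at least 2-fold higher and 243 lower, and between 10 and 100 RPKM 242 of 4572 were higher and 454 lower. Between 100 and 1000 RPKM the order turned, with 122 of 974 genes higher and 76 lower. Of the 75 genes at 1000 RPKM or more, 9 were higher and 17 lower.

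**Figure D1:**
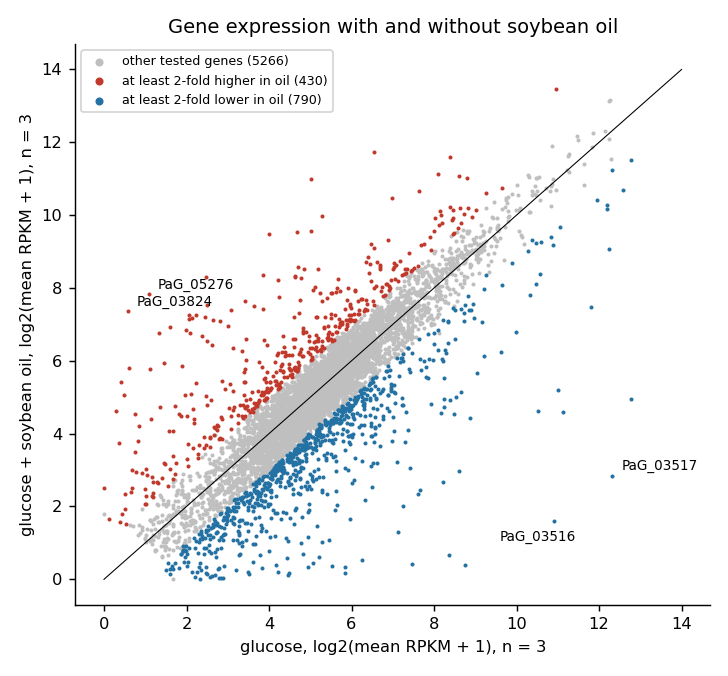
Mean expression of the 6486 tested genes, as log2(mean RPKM + 1), on glucose (horizontal axis, n = 3) and with soybean oil (vertical axis, n = 3). Each point is a gene: 430 genes at least 2-fold higher with oil (red) lie above the line of equal expression, and 790 at least 2-fold lower (blue) lie below it. The 2 strongest rises and 2 strongest falls among genes of at least 10 RPKM without overlap between groups are labelled.

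The files identify genes by number and do not pair the identifiers with names or products, so the 2 strongest rises and the 2 strongest falls are given by identifier. PaG_03824 rose from 0.486 ± 0.0681 RPKM on glucose to 165 ± 59.3 with oil (SD, n = 3), a log2 fold change of 6.73 (SE 0.27, limma adjusted p 1.0e-06). Its glucose values rested on 10, 11 and 12 reads. PaG_05276 rose from 1.11 ± 0.179 to 227 ± 62.1 RPKM (SD, n = 3), a log2 fold change of 6.72 (SE 0.20, limma adjusted p 2.58e-07). PaG_03517 was among the 5 most abundant glucose transcripts and dropped from 5118 ± 1746 to 6.18 ± 0.401 RPKM (SD, n = 3), a log2 fold change of -9.41 (SE 0.25, limma adjusted p 1.57e-07). The next identifier down, PaG_03516, dropped from 1912 ± 587 to 2.02 ± 0.347 RPKM (SD, n = 3), a log2 fold change of -9.26 (SE 0.23, limma adjusted p 1.22e-07). All 4 changes were in the same direction in the stranded pair of replicate 1, whose unstranded libraries had helped pick these genes. In that pair PaG_03824 stood at 0.98 and 296.56 RPKM and PaG_03517 at 2940.34 and 12.48.

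**Figure D2:**
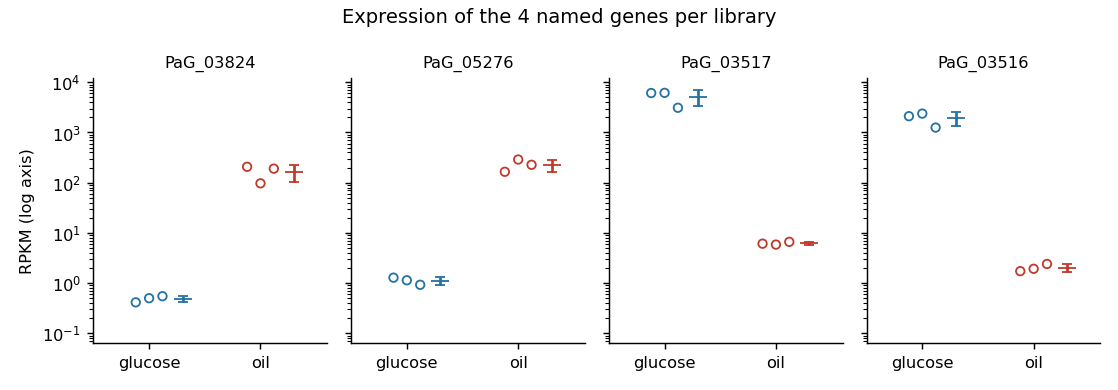
RPKM (log axis) of PaG_03824, PaG_05276, PaG_03517 and PaG_03516 in each of the 3 glucose (blue) and 3 soybean oil (red) libraries, shown as circles, with the mean and SD beside them. The first pair rose from about 1 RPKM or less to means of 165 and 227, and the second pair fell from means of 5118 and 1912.

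The glucose libraries were not equally alike. Replicates 1 and 2 correlated at r = 0.994 across genes, which are not independent replicates, and replicate 3 correlated with them at 0.967 and 0.970. The soybean oil libraries correlated at 0.982 to 0.989. Among the 171 genes of at least 10 RPKM that fell at least 4-fold in the limma test without replicate 3, this replicate lay beyond both others in the direction of the oil values in 134 (78.4%). Among the 112 genes that rose at least 4-fold it did so in 46 (41.1%). The sample titles mark the replicates as br, the usual short form of biological replicate, but nothing in the labels says whether they came from separate cultures, so the p-values measure the spread between these samples. Putting the paired-end library in place of the 50 bp library of soybean oil replicate 2 left 761 changed genes, 547 of them at least 2-fold. Quantile normalization turned the 430 higher and 790 lower genes into 517 and 568.

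The next comparison asked whether changed genes lay side by side, since smut fungi keep the genes of glycolipid synthesis in clusters. The order of the identifiers was used in place of map positions, which the gene files do not give. Genes with consecutive identifiers rose together in 59 pairs, where 24.7 were expected by chance (2.39 times), and fell together in 134 pairs, where 83.5 were expected (1.6 times). The permutation p was 1e-04 for both, one-sided, the smallest that 10000 random orders can give. The excess faded with distance: at an identifier difference of 5 the ratios were 1.35 (permutation p 0.0438) and 1.0 (permutation p 0.512), and at 10 they were 0.938 and 0.934. It was present among the 5547 tested genes of the main identifier series, with ratios of 2.56 and 1.75 (permutation p 1e-04 for both). In the separate series numbered above 10000, which held 939 tested genes, the ratios were 1.5 (permutation p 0.201) and 0.812 (permutation p 0.811). The difference between the series was not tested.

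PaG_03824 belonged to a run of 6 consecutive identifiers that all rose at least 2-fold, the longest such run. Their log2 fold changes ranged from 2.02 to 6.73 and their means from 0.336 to 4.47 RPKM on glucose and from 6.62 to 165 with oil. PaG_05276 was the first of a run of 5 with log2 fold changes of 3.85 to 6.72 and means of 138 to 377 RPKM with oil. Another run of 5 had log2 fold changes of 2.46 to 5.17 and reached 3378 RPKM with oil, and a run of 4 had 2.35 to 4.52. Chance gave a mean of 0.062 runs of at least 4 risen genes and at most 1 in 1000 random orders, against the 4 observed. Runs of at least 4 fallen genes numbered 6 and held 26 genes, where chance gave a mean of 0.829 and at most 5. PaG_03516 and PaG_03517 fell as a pair: the next identifier above them had a log2 fold change of -0.07 (limma adjusted p 0.816), and the next below was too weakly expressed to be tested.

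**Figure D3:**
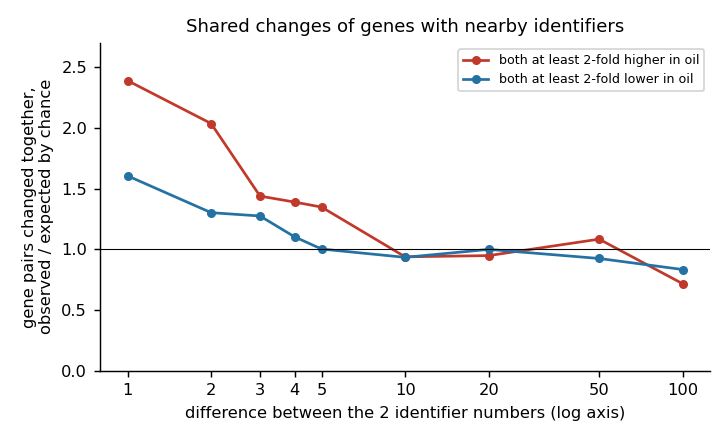
Number of gene pairs that both rose (red) or both fell (blue) at least 2-fold, divided by the number expected by chance, against the difference between their identifier numbers (log axis). The ratios start at 2.39 and 1.6 for consecutive identifiers and lie at 0.938 and 0.934 at a difference of 10; the black line marks 1.

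The splice junctions, the introns inferred from reads that span them, served the annotation of transcripts. Most spliced reads came from a core of short introns: 2312 introns were listed in all 6 main libraries and carried 94.8% of their junction reads. The median length of these introns was 85 nt (quartiles 75 and 109.25), the shortest was 50 nt, and 1154 lay on the plus and 1158 on the minus strand of 24 scaffolds. Of the 2312, 2309 (99.9%) were also listed for the paired-end library and 2170 in a list of a stranded library. A library listed 3785 ± 77 junctions on glucose and 3718 ± 116 with oil (SD, n = 3). At equal junction reads, in 1 random thinning, it listed 3734 ± 25 (3709 to 3759) on glucose and 3596 ± 19.5 (3582 to 3618) with oil (SD, n = 3), without overlap, which chance gives in 10% of cases. Junctions spanned 1.88% ± 0.0567 of the reads on glucose and 2.00% ± 0.162 with oil (SD, n = 3; two-sided exact permutation p 0.3, where 3 against 3 cannot go below 0.1). Of the 8340 junctions in any of the 6 libraries, 4938 were in 1 library only, with a median of 1 read, and 78.9% of these spanned more than 1000 nt. A missing junction is no proof that an intron was not spliced: of 1899 junctions with at least 20 reads in a glucose library, 117 (6.16%) were absent from another glucose library, and of 1935 in oil libraries 132 (6.82%).

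Reads across introns give positions to the changed transcripts. The strongest named rise was in an intron of scaffold 6 (positions 289785 to 289850, minus strand), from 17.3 ± 2.89 to 1195 ± 161 reads (SD, n = 3), a log2 fold change of 5.94 (edgeR adjusted p 1.37e-06). On scaffold 20 the neighbouring introns at 3914 to 3998 and 4331 to 4423 (minus strand) rose from 47.0 ± 4.36 to 1468 ± 169 and from 47.3 ± 9.02 to 1325 ± 200.4 reads (SD, n = 3). The strongest fall was on the same scaffold, at 31000 to 31077 (plus strand), from 2246 ± 913 to 2.33 ± 1.15 reads (SD, n = 3), a log2 fold change of -9.96 (edgeR adjusted p 3.99e-06). It was followed by the intron of scaffold 3 at 450433 to 450520 (plus strand), which fell from 915 ± 120.2 to 12 ± 4.58 reads (SD, n = 3), a log2 fold change of -6.37. These introns were chosen after the data were examined, among those listed in all 6 libraries with at least 100 reads. The genome build is not given in the sources used here, and the files do not link positions to gene identifiers.

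A stretch of 35 kb on scaffold 2, from 2017127 to 2052526, held 12 tested introns in 5 loci, all on the minus strand and all at least 2-fold higher with oil. Their log2 fold changes ranged from 2.14 to 6.0, and the largest edgeR adjusted p was 0.000745. Together they had 76.3 ± 21.4 reads on glucose and 1767 ± 527 with oil (SD, n = 3). The intron at 2017917 to 2018016 rose from 6.33 ± 3.51 to 292 ± 67.0 reads (SD, n = 3). The stretch was picked out after the data were examined, since no window of 50 kb held more risen loci and all of its loci had risen.

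**Figure D4:**
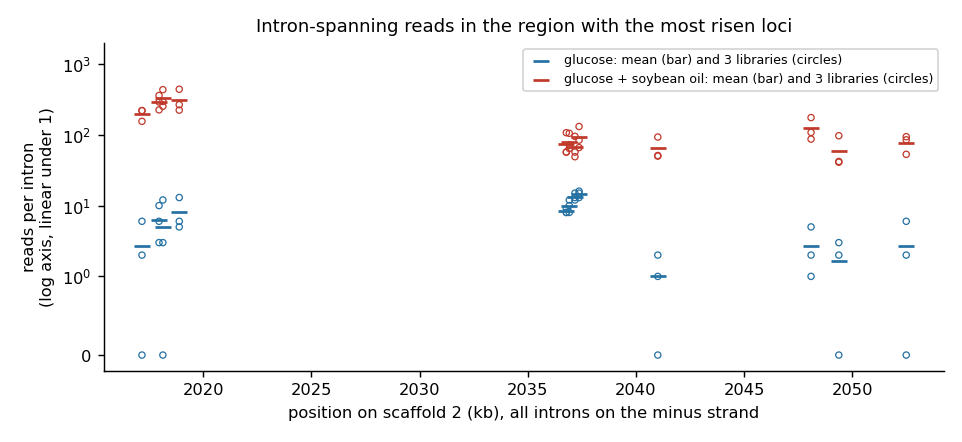
Reads spanning each of the 12 tested introns between 2017127 and 2052526 of scaffold 2 (horizontal axis in kb) in the 3 glucose (blue) and 3 soybean oil (red) libraries, as circles with the mean as a bar, on an axis that is logarithmic above 1 and linear below. Every intron had more reads in each soybean oil library than in any glucose library, and the sums were 76.3 and 1767.

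In all, edgeR called 492 of 2270 tested introns changed, 222 higher and 270 lower, and 779 had an unadjusted p under 0.05. Of the changed introns 439 were listed in all 6 libraries, and among these 108 rose and 174 fell at least 2-fold. The count was sensitive to single libraries: it was 304 without glucose replicate 1, 285 without glucose replicate 2, 316 without soybean oil replicate 1 and 304 without soybean oil replicate 3. DESeq2 called 368 of the 2270.

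The last test asked whether the medium changed which of several competing splice sites was used. Among sites whose junctions were listed in all 6 libraries, the shift with the smallest p was at the donor at position 177972 of scaffold 23 (minus strand), which was joined to acceptors at 177445 and 177447. The acceptor at 177445 took 39.5% ± 1.94 of the site's reads on glucose and 63.2% ± 2.18 with oil (SD, n = 3). It had 337 and the other acceptor 232 reads in the paired-end soybean oil library. In the planned test on 244 sites, each with at least 2 junctions of at least 10 reads, edgeR called 0 sites, with 11 at an unadjusted p under 0.05 and a smallest adjusted p of 0.527. The outcome depended on which junctions entered, in alternatives chosen after the data were examined. With junctions listed in all 6 libraries alone, 1 of 25 sites was called, the donor on scaffold 23 (edgeR adjusted p 0.0122, against 0.935 in the planned test). Without junctions that had at least 20 reads in a library and were absent from another of the same group, 2 of 175 sites were called, donors at 1082587 of scaffold 2 (edgeR adjusted p 1.03e-05) and 245997 of scaffold 21 (edgeR adjusted p 0.00208). This removal used the media as groups. It took out junctions that varied within a medium and kept those absent from a whole medium, which favours small p-values by construction. Without glucose replicate 2 the planned test called 1 of 216 sites. No other tool was run on these sites, and the planned test's 95% recovery of 4-fold shifts was measured on simulated data without missing junctions. The changed sites of that simulation had 2 junctions of at least 100 reads each, so recovery at weaker sites was not measured.

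The library kinds were compared to see how far the values depended on preparation and sequencing. The response to soybean oil was alike in both preparations of replicate 1: the fold changes of the stranded and unstranded pairs correlated at r = 0.934 (Spearman's rho 0.890) across 6484 genes, which are not independent replicates. Of the 1220 genes changed at least 2-fold in the main comparison, 1195 (98.0%) had the same direction in the stranded pair. The unstranded libraries of replicate 1 had helped pick these genes for large changes, so this share is high in part by construction. Levels differed more. The stranded and unstranded libraries of one replicate correlated at r = 0.839 (rho 0.847) on glucose and 0.881 (rho 0.907) with oil. The paired-end and 50 bp libraries of soybean oil replicate 2 correlated at 0.886 (rho 0.877) and differed at least 2-fold in 1306 of 6486 genes (20.1%). Between pairs of the 50 bp soybean oil libraries, 40 to 151 genes differed that much. The stranded kind had 1 library per medium and the paired-end kind 1 library, with soybean oil, so these differences were not tested across replicates.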

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

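Both results here lie in libraries outside the main comparison and were picked out because they showed a signal that the 6 main libraries lacked. The limits used for them (16 times the highest main library, 10 RPKM and 5 reads) were chosen after the data were examined. No test across replicates was run, with 1 stranded library per medium and 1 paired-end library, from soybean oil replicate 2. In the stranded libraries, 39 genes stood in both media at no less than 16 times the highest value of any of the 6 main libraries and at no less than 10 RPKM. Of these genes, 37 belonged to the identifier series above 10000. Their median length was 261 bp, against 1664 bp for all other genes. They made up 53.3% of the summed RPKM of the stranded glucose library and 42.1% of that of the stranded soybean oil library, but 0.350% and 0.254% in the unstranded libraries of the same replicates. The highest value was 203517 RPKM in the stranded glucose library and 173395 RPKM in the stranded soybean oil library, against 11655 RPKM in the main libraries.

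The paired-end library of soybean oil replicate 2 listed 3770 junctions found in no other library, of which 1240 had at least 5 reads. The median intron of these 1240 was 107.5 nt long, against 85 nt for the introns listed in all 6 main libraries. Junctions spanned 8.02% of this library's reads, against 1.82% to 2.14% in the main libraries, and it held 31573726 reads. Its junction reads numbered 2532134, against 163851 to 224962 in the main libraries. Its reads were 95 bp and paired, where the main libraries had 50 bp single reads. More and longer reads list more junctions by construction, and this library was not thinned to equal reads. Its numbers are therefore not on the same footing as those of the main libraries.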

How the results depend on the processing

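The substitution of the paired-end library, the removal of introns missing from 1 library of a group, the splicing test on introns listed in all 6 libraries, and the block and quantile versions of the neighbour test were chosen after seeing the data; the other alternatives were planned. Of 270 values under alternatives, 254 were classed as kept in direction and in size or side of the threshold, 16 as moved and 0 as reversed. This tally does not measure how stable the results are. Of the 254, 68 and 120 belong to the genes and introns given next, which were picked for their large changes. Among counts, shifts such as from 3210 to 2480 genes and from 492 to 358 introns were still classed as kept. The 4 named genes kept their direction and an adjusted p under 0.05 in 68 of 68 values (largest adjusted p 0.000934), and the 12 introns chosen for the size of their change, 6 risen and 6 fallen, in 120 of 120 (largest 0.0231). The size of the named rises depended on the setting. The log2 fold change of PaG_03824 was 4.88 with a pseudocount of 5 RPKM and 8.49 with DESeq2, and that of PaG_05276 was 5.21 and 7.73. The count of 3210 changed genes lay between 2480 and 3644 when a library was left out, the highest without glucose replicate 3, and was 3436 with edgeR and 3543 with DESeq2 on recovered reads. Genes changed at least 2-fold numbered 1153 to 1333 with a library left out, and 808 with a pseudocount of 5 RPKM, which shrinks the fold changes of weakly expressed genes by construction. With the paired-end library in place of soybean oil replicate 2 the counts were 761 and 547. Of the genes called in the main fit, 19 had the other direction in this fit, whether or not it called them. The cause was not tested. Quantile normalization moved the median log2 fold change from -0.06 to 0.02 and gave 517 higher and 568 lower genes. Of the genes called in the main fit, 3 had the other direction after it.

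Genes with consecutive identifiers rose together 2.16 to 2.65 times as often as by chance with a library left out, and fell together 1.55 to 1.62 times. With genes called by the adjusted p alone, without the limit on size, the ratios were smaller, at 1.24 and 1.19 (permutation p 1e-04 for both). Counting junctions with at least 5 reads gave 2657 per glucose and 2614 per soybean oil library, and thinning to equal junction reads gave 3734 per glucose and 3596 per soybean oil library; fewer reads list fewer junctions by construction. The count of 492 changed introns ranged from 285 to 484 with a library left out (304, 285 and 484 without glucose replicates 1, 2 and 3, and 316, 367 and 304 without soybean oil replicates 1, 2 and 3), where fewer samples were tested. It was 368 with DESeq2, 594 without the filter and 592 without the introns missing from 1 library of a group. That removal used the media as groups and took out introns that varied within one, so more calls follow in part by construction. Splice site calls ranged from 0 to 1 with a library left out, the 1 without glucose replicate 2; they were 2 of 175 sites without the introns missing from 1 library of a group and 1 of 25 with introns listed in all 6 libraries. With a pseudocount of 0.1 RPKM the correlations between library kinds became 0.890 (stranded, soybean oil), 0.876 (paired-end) and 0.929 (fold changes); the cause was not tested. The replicate number as a block gave 2973 changed genes, 1217 of at least 2-fold, 358 introns and 0 splice sites. Deviations of same-numbered libraries correlated at -0.19, 0.23 and 0.05, which leaves open whether the numbers pair the samples. The planned tests of 28 gene lists were not run, since no list could be matched to the identifiers.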

Other observations

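The tests on the scaffold regions, on glucose replicate 3, on the order of the identifiers and overlapping neighbours, on admixture and the wrong label for the paired-end library, and the counts over other splits of the samples were chosen after the results were seen; those on gene length and on near-identical copies were set out before. Near the start of scaffold 2, a stretch of 48 kb from 42072 to 89891 held 16 tested introns, 12 of which fell at least 2-fold with soybean oil. Reads of these 12 introns summed to 769 ± 158 on glucose and 253 ± 57.3 with oil (SD, n = 3). The 4 introns between 42072 and 46743 had 11 to 51 reads in each glucose library and were listed in none of the 3 unstranded 50 bp soybean oil libraries, nor in the stranded one. The paired-end library listed 3 of them, with 29, 23 and 13 reads. In the same stretch the introns at 63846 to 63948 and at 64158 to 64249 had log2 fold changes of 0.03 (edgeR adjusted p 0.956) and -0.04 (edgeR adjusted p 0.944).

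Among the fallen introns listed in all 6 libraries were also scaffold 20 at 135423 to 135644 (370 ± 156 to 23.7 ± 10 reads), scaffold 18 at 338165 to 338646 (92.0 ± 16.4 to 6 ± 3.46), scaffold 10 at 442702 to 442767 (113 ± 70.3 to 8 ± 6.93) and scaffold 17 at 46325 to 46414 (174 ± 19.1 to 12.7 ± 1.53), all SD with n = 3. Their log2 fold changes were -4.10, -4.10, -3.94 and -3.92, and that on scaffold 10 was -4.74 without soybean oil replicate 2. In the paired-end soybean oil library they had 1001, 116, 1688 and 168 reads, out of 2532134 junction reads there and 224962 in the 50 bp library of that replicate. Relative to each library's junction reads, the scaffold 10 intron there lay within the range of the glucose libraries, so its fall did not show. The glucose libraries had 171, 134 and 35 of its reads out of 192243, 170310 and 163851, and the 50 bp library had 16. On this scale the other introns stayed below every glucose library. A few introns, chosen after their values were seen, were listed in the 3 main libraries of a single medium or in some of them, and the other libraries did not always follow. On scaffold 2 the donor at 1082587 (minus strand) was joined over 4063 nt in 26, 31 and 28 reads of the glucose libraries and in none of the soybean oil libraries, stranded and paired-end ones included, nor in the stranded glucose library. It made up 14.7% ± 2.71 (SD, n = 3) of the site's glucose reads. On scaffold 21 an intron of 19371 nt from 245997 had 18, 29 and 20 reads in the main soybean oil libraries and none in the 3 main glucose libraries, but 12 in a list of the stranded glucose library and none in the stranded and paired-end soybean oil libraries. On scaffold 16 the donor at 398109 (plus strand) was joined to 398318 in 90, 47 and 67 reads of the main soybean oil libraries, 234 of the paired-end one and none of the glucose libraries. Its junction to 398395 had 205, 0 and 132 reads on glucose and none in the 50 bp unstranded soybean oil libraries, but 1990 in the paired-end one. In the lists of the stranded libraries the junction to 398318 had no reads, and that to 398395 had 2 and 0 on glucose and 0 and 3 with oil. None of these sites passed the planned splicing test (smallest edgeR adjusted p 0.527). Those on scaffolds 2 and 21 passed it without junctions missing from 1 library of a group, a removal that favours calls by construction. Junctions with such read numbers were also missing from single replicates of one group.

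Glucose replicate 3 lay between its group and the soybean oil libraries for part of the genes. Over the 171 genes of at least 10 RPKM that fell at least 4-fold from glucose replicates 1 and 2 to oil, it lay a median of 39.4% of the way to the oil mean (quartiles 16.3% and 55.2%). RNA of a soybean oil culture mixed into this library would raise the risen genes by an equal share, but over the 112 risen genes the median was -0.125% (quartiles -1.85% and 2.21%). Few reads do not account for it either, since its chi-square per gene against the other glucose libraries was no less than 87.5, where replicates 1 and 2 had 6.84 against each other, and its total was not the lowest of the 6. A culture further along in the loss of glucose-phase transcripts may be a candidate explanation, but no biological explanation was tested.

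The paired-end library of soybean oil replicate 2 differed from the 50 bp library of that replicate, with 1020 genes at least 2-fold higher and 286 lower, and its difference correlated across genes with the response to oil of soybean oil replicates 1 and 3 at r = -0.457. Admixed RNA from a glucose culture would shift both kinds of genes alike, but genes of at least 10 RPKM that were at least 16-fold lower with oil, called without replicate 2, lay a median of 6.44% of the way from the 50 bp library to the glucose mean (quartiles 0.323% and 17.6%), and genes at least 16-fold higher 62.1% (quartiles 31.4% and 90.9%), which argues against it as the whole cause. Gene length took up 0.921% of the variance of the difference. The 6.44% also argues against a glucose library under the wrong label, which would lie near the glucose mean, while similarity over all genes was mixed: r was at most 0.830 with glucose and 0.854 to 0.886 with soybean oil libraries, but 1241 genes were at least 2-fold apart from glucose replicate 1 and 1306 from the 50 bp library of its own replicate. A different culture or RNA sample under the same number, or an effect of the library preparation, stays open, and no biological explanation was tested.

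Genes with consecutive identifiers changed in the same direction more often than by chance, with a permutation p of 1e-04 for pairs that rose, the smallest that 10000 random orders can give. Reads counted for both of a pair of overlapping genes would act on direct neighbours alone, but pairs at an identifier difference of 3 still rose together 1.44 times as often as by chance (permutation p 0.02). How much such reads add to the larger excess among direct neighbours stays open. Near-identical copies that share reads would have about equal levels, but the median fold between members of the 193 pairs was 2.51 (quartiles 1.47 and 7.09); for the 51 pairs (26.4%) under 1.5-fold this stays open. Groups of neighbouring genes that share a response to the medium are a candidate explanation. The intron positions were used as a further test of it, on reads of the same 6 libraries, so it is not independent evidence. Introns of 1 transcript that lie more than 2000 nt apart count as separate loci, which can add pairs that changed together. Of 987 pairs of loci within 10 kb, 8 rose together where 3.11 were expected (permutation p 0.0161, highest count in 10000 random assignments 11) and 16 fell together where 9.95 were expected (permutation p 0.0474, highest 26), and because the limit set for this test was a count above every random assignment, it left the question open.

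Dividing the 6 libraries into groups of 3 can be done in 10 ways, too few for a share under 0.05. Every split but the real one puts both media in each group. The difference between media then widens the spread within groups, so few calls follow by construction. The counts over splits therefore do not measure how often chance gives as many. The real split alone, 1 of 10, gave as many changed genes (3210, highest other 1), as many genes of at least 2-fold (1220, highest other 1) and as many changed introns (492, highest other 1). For splice sites the real split gave 0 and the highest other 0, so all 10 gave as many.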
